A study of Drosophila melanogaster with 4 samples.

How the data were processed

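RNA from adult Oregon-R females of Drosophila melanogaster was compared on 4 spotted arrays with 2 dye channels each. Per the labels' protocols, flies received 2 mL of a black pepper (Piper nigrum) seed extract at 0.9 mg/mL in 99% ethanol, or 2 mL of 99% ethanol alone, from a Potter's tower (a spray tower for even topical application). Per the labels, sampling followed after 4 h, each pool held about 240 females, and 80 µg of total RNA was labelled directly with Cy3 or Cy5. The labels number the replicate pools 1 and 3, and each pool was hybridised a second time with the dyes exchanged. The 2 arrays of a pool were therefore counted as 1 replicate, which gives n = 2. The series design describes a pool as insects treated together, so p-values measure the spread between 2 such pools.

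The values used were the log2 ratios the authors deposited, 1 per spot for 16896 spots on each array, with no missing value. The log base was not given in the sources used here and was taken as 2; with another base every size below would scale by 1 factor. The scanner, background correction, normalization and spot filters of the authors were not given in the sources used here. Array medians lay at -0.00218, -0.000152, -0.00103 and -0.000177, in the order replicate 3 with extract in Cy3, replicate 1 with extract in Cy3, replicate 3 with extract in Cy5 and replicate 1 with extract in Cy5. Channel 1 held ethanol and channel 2 extract on all 4 arrays, per the labels, whichever dye was used.

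The numerator of the ratio was not given in the sources used here. A rule fixed before the data were examined read it from the 2 arrays of each dye swap: r below -0.1 in both pools meant ratios by dye, r above 0.1 in both meant ratios by treatment. The 2 values were 0.0632 for replicate 3 and 0.0211 for replicate 1, so neither case applied, and the ratios were read as deposited, channel 2 over channel 1. This direction was assumed and is not settled. Ratios by treatment with ethanol on top would reverse every sign below. If the ratios were deposited by dye, the reading with the 2 reverse-label arrays turned would hold the effect of the extract. It is given as an alternative. Its sign would depend on the dye on top: Cy3 over Cy5 would make it extract over ethanol, and Cy5 over Cy3 ethanol over extract.

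Each array was centred on its median, which moved no array by more than 0.0022. Gene symbols came from the platform's annotation, which lists 1 gene for 5666 spots (33.5%), several genes for 152 and none for 11078. The symbols were checked by gene number against NCBI RefSeq's gene table of assembly GCF_000001215.4 (Release 6), with 5666 matched and 0 changed; coordinates were not used here. Spots of 1 gene were averaged per array (2377 genes, median 2 spots), and all other spots stayed single features, giving 13607 features. The dye swaps were averaged per pool, and the log2 ratio was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The fit had 1 residual degree of freedom and 8.19 prior degrees of freedom, with a median standard error of 0.153. An exact sign test on 2 pools cannot go below a two-sided p of 0.5, so every call rests on the variance that limma shares across features. The number of arrays limits the precision, and signal over background was not used here.

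A count with no model took features with 1 sign on all 4 arrays and at least 2-fold in both pools. The 29 gene lists were fixed before the data were examined. The 11 with at least 5 measured genes were tested among the named genes with limma's camera, adjusted over those lists. Camera used a preset correlation of 0.01, with an estimated correlation and fry as alternatives. With 2 pools the estimated correlation rests on 1 residual degree of freedom, so a call lost with it decides little. The lists covered detoxification (cytochrome P450, insecticide-associated P450, glutathione S-transferase, UDP-glycosyltransferase, carboxylesterase), stress and immunity (antioxidant and CncC/Keap1, heat shock protein and chaperone, endoplasmic reticulum and integrated stress response, cell death and JNK, antimicrobial peptide and immune, Turandot) and digestion (lysozyme, gut serine protease, glycoside hydrolase and sugar digestion). Others covered metabolism and translation (glycolysis, lipid storage and fatty acid synthesis, oxidative phosphorylation, cytoplasmic ribosomal protein, mitochondrial ribosomal protein) and tissues or functions (eggshell and yolk, germline of the ovary, male accessory gland and testis, photoreceptor, neuronal and synaptic, TRP and other ion channels, muscle, cuticle, odorant-binding protein, circadian clock). A list of 8 fasting and autophagy genes was added after the gene table had been seen.

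Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest genes past the test with 1 sign on all 4 arrays, filled up with genes at 2-fold in both pools and then by smallest p, plus all measured genes of 21 fixed candidates and up to 3 genes of smallest p per list. Other settings fixed before the data were examined were the other sign of the reverse-label arrays, no centring, equal spread, the replicate block as a random effect with and without a dye term (statmod 1.5.0), single spots, the median of a gene's spots, robust eBayes, a looser threshold or fold, and each array and pool left out. Averaging of all adjacent spots, named genes alone, a filter on duplicate spots, the muscle list without its 1 or 2 highest genes and the turned lists with the other set tests were added after the data were seen. The steps were tested on simulated data made by randomising the signs of the real ratios for each pair of adjacent spots on each array. With 50 features changed at each size among 13607, limma recovered 0% at a log2 change of 0.5, 70% at 1, 100% at 1.5 and 100% at 2, with 5 false among 140 calls. All sizes were changed in the same set, and so many calls loosen the Benjamini-Hochberg cutoff. These shares are therefore not the power in the data, which gave 6 calls, the smallest at a log2 size of 1.33. In 100 draws with no change, 15 had any call, with at most 48, and 15 had a gene list past the test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.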

Results

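The data were 4 arrays of 16896 spots that set females sprayed with pepper extract against females sprayed with ethanol, in 2 pools with a dye swap each. The series title names Piper nigrum as a botanical insecticide, and the comparison asks which transcripts differed 4 h after contact with the extract. Values are log2 ratios of extract over ethanol, channel 2 over channel 1, with the standard error of limma and n = 2 pools throughout. This direction was assumed and is not settled, and ratios of ethanol over extract would reverse every sign below. If the ratios were deposited by dye, the ratios that repeat below would be dye effects, and 4 arrays of ratios cannot tell these apart. The values given with the reverse-label arrays turned would then hold the effect of the extract, with a sign that depends on the dye on top. Of the 83 genes named by the rules, 48 changed sign or moved by over 1.5 times without 1 of the arrays. Single ratios below may therefore rest on 1 array. Cyp12d1-p, the only named gene past the test, was not among the 48, but its call was lost without the Cy3 array of replicate 3.

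Cyp12d1-p, a mitochondrial cytochrome P450 known for its link to insecticide resistance, rose by 1.33 ± 0.16 on the log2 scale (limma, adjusted p = 0.0315). It lay at 1.19 in replicate 1 and 1.47 in replicate 3, above 0 on 4 of 4 arrays, and was the only named gene among 6 features past the test. The flight-muscle actin Act88F had a ratio of 1.13 ± 0.15 (limma, adjusted p = 0.0506). CG11893, of the ecdysteroid kinase-like family, stood at 1.09 ± 0.15 (limma, adjusted p = 0.0604). These 3 were the named genes at 2-fold or more in both pools.

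Of the 13607 features, 6 passed the limma test, 4 higher and 2 lower with extract, and 5 of them were spots with no gene name here. Among these 5 spots, 2 adjacent pairs passed with both spots, and adjacent spots share a gene wherever the annotation names them, so the 6 calls cover 4 pairs or genes and both lower calls are 1 pair. The spots numbered 16055 and 8103 rose by 1.90 ± 0.24 and 1.68 ± 0.15, and spots 5482 and 5481 fell, at -1.55 ± 0.15 and -1.42 ± 0.15. At an unadjusted p under 0.05 there were 999 features, 600 higher and 399 lower. They were 908 of 11230 single spots and 91 of 2377 named genes. The fit shared its prior variance between single spots and gene means, so the 2 kinds were not called on equal terms. The median standard error was 0.153 in this fit and 0.127 with named genes alone. Features at 2-fold or more in both pools numbered 9, with 7 higher and 2 lower, and those at 1.5-fold or more 68, with 54 higher and 14 lower. All 6 calls were lost without the Cy3 array of replicate 3, where Cyp12d1-p stood at 1.19 (limma, adjusted p = 0.629), and with the reverse-label arrays turned, where it stood at 0.06 (limma, adjusted p = 0.984). These 2 settings left 835 and 647 features at an unadjusted p under 0.05. Turned, the 647 split into 324 above 0 and 323 below, and 14 features were at 1.5-fold, 4 above 0 and 10 below. With arrays scaled to equal spread, 42 features passed, 36 higher and 6 lower, and with the 4 arrays and the replicate block 12 passed, 8 higher and 4 lower. The block fit used a correlation of -0.244 between arrays of a pool, so it did not hold them as 1 replicate.

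The other genes that the naming rule took above 0, by 1 sign on all 4 arrays and smallest p, missed the test. CG31904 stood at 1.18 in replicate 1 and 0.83 in replicate 3. The phosphoserine phosphatase gene aay, of serine synthesis, had a ratio of 1.03 ± 0.18 and Vajk3 of 0.89 ± 0.15. CG5966, a predicted triacylglycerol lipase, stood at 0.90 ± 0.17, and Lpin, the phosphatidate phosphatase lipin, at 0.73 ± 0.16. CG13868, Jhbp5, betaNACtes3 and CG9297 lay at 0.71, 0.72, 0.65 and 0.60, with betaNACtes3 at 0.30 without the Cy5 array of replicate 3. With named genes tested alone, a setting added after the data were seen, 10 of 2377 passed: Cyp12d1-p, Act88F, CG11893, CG31904, Vajk3, aay, CG5966, CG13868 and Lpin, all higher, and CG8745, which was lower. Of 100 draws with no change, 3 gave at least 10 calls under that setting.

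No named gene passed below 0 over all features in limma, where 91 named genes of either sign had an unadjusted p under 0.05. CG8745, a predicted aminotransferase, stood at -0.73 ± 0.15 (limma, adjusted p = 0.227), with -0.67 in replicate 1 and -0.79 in replicate 3, and at -0.13 with the reverse-label arrays turned. The 4 named genes with lower means did not keep 1 sign on all 4 arrays. The lipophorin precursor apolpp stood at -0.54 ± 0.18, CG42750 at -0.53 ± 0.15 and CG8531 at -0.48 ± 0.15. Of 190 named genes below 0 on all 4 arrays, those of next smallest p included CG8654 at -0.46, ChLD3 at -0.44, CG15170 at -0.41, Sgt, a co-chaperone, at -0.40, pch2, a meiotic checkpoint gene, at -0.40 and the myoinhibitory peptide precursor Mip at -0.39. Kdsr, an enzyme of sphingolipid synthesis, lay at -0.36 and Jabba, which anchors histones on lipid droplets, at -0.35.

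**Figure D1:**
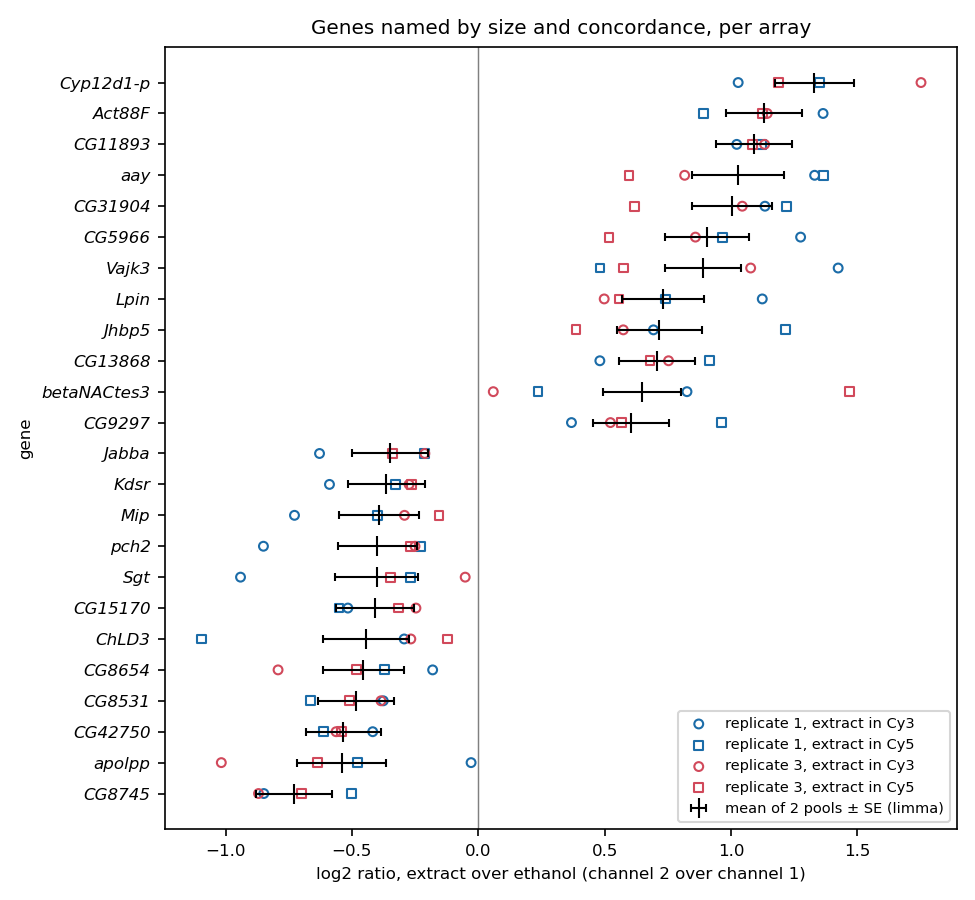
Log2 ratio of extract over ethanol (x axis) for the 24 genes named by the size rule (y axis), with 1 open symbol per array and the mean of 2 pools with the limma standard error in black. Cyp12d1-p lies furthest right at 1.33 and CG8745 furthest left at -0.73, and each gene has 1 sign on all 4 arrays by the rule that chose it.

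Detoxification genes were thinly covered, with Cyp12d1-p the 1 measured gene of the 21 fixed candidates. Of 4 measured cytochrome P450 genes, 1 rose, Cyp12d1-p, both over all features and adjusted over the list alone. The others did not pass: Cyp4ac1 stood at -0.33 ± 0.18, Cyp4g15 at 0.14 ± 0.15 and Cyp6u1 at -0.06 ± 0.17. Cyp12d1-p and Cyp6u1 were also the 2 measured genes of the insecticide-associated P450 list, where 1 passed over all features and 1 adjusted over the list alone. Cyp12d1-d, a near-identical neighbouring copy, was not measured under its own name, and a spotted probe can bind both transcripts. The glutathione S-transferases GstE2, GstE13 and GstZ2 lay at 0.10, 0.09 and -0.06, with 0 of 3 past the test over all features and 0 adjusted over the list alone. Of 7 UDP-glycosyltransferases, 0 passed over all features and 0 adjusted over the list alone, with Ugt50B3 at -0.31, Ugt37E1 at -0.30 and Ugt37A1 at -0.22 (limma camera, adjusted p = 0.363). The first 2 each rest on 1 array: without the Cy3 array of replicate 3 Ugt50B3 stood at 0.08, and without the Cy5 array of replicate 1 Ugt37E1 stood at 0.09. The list median of -0.02 became 0.07 and 0.09 without these arrays. No carboxylesterase was measured under a gene name here.

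In the antioxidant and CncC/Keap1 list, Keap1, which represses the detoxification regulator CncC, stood at 0.50 ± 0.16 (limma, adjusted p = 0.525). TrxT lay at -0.25 and Sod3 at -0.18, and of 9 genes 0 passed over all features and 0 adjusted over the list alone (limma camera, adjusted p = 0.981). Of 5 heat shock and chaperone genes, the co-chaperone stv stood at 0.37 ± 0.15, Hsc70-2 at -0.28 ± 0.23 and DnaJ-1 at -0.06. With the reverse-label arrays turned, stv stood at 0.19 and Hsc70-2 at 0.57, and without the Cy5 array of replicate 1 Hsc70-2 stood at 0.22. None of the 5 passed over all features or adjusted over the list alone, with 1 at an unadjusted limma p under 0.05, and the list did not pass (limma camera, adjusted p = 0.981). In the turned reading this was the 1 list past the test, with a median of 0.38 (limma camera, adjusted p = 0.000516). It did not pass with an estimated correlation (limma camera, adjusted p = 0.998) or with fry (limma fry, adjusted p = 0.881). The estimate has 1 residual degree of freedom, so its lost call decides little. Of 8 genes of the endoplasmic reticulum and integrated stress response, 7 lay below 0, with Gp93 at -0.32, ERp60 at -0.15 and Pdi at -0.14. Their median was -0.12, and 0.01 with the reverse-label arrays turned, where 3 lay below 0, with 0 past the test over all features and 0 adjusted over the list alone (limma camera, adjusted p = 0.185).

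Among 4 measured cell death and JNK genes, puc, a phosphatase induced by JNK signalling, stood at 0.46 ± 0.15 (limma, adjusted p = 0.557). kay, the fly Fos, lay at 0.36 ± 0.15 and p53 at -0.29 ± 0.15, with 0 past the test over all features and 0 adjusted over the list alone. The immune list held 1 measured gene, Dif, at -0.20, and the Turandot list TotF at 0.04, with 0 past the test in each over all features and adjusted over the list alone. No lysozyme, gut serine protease or sugar digestion gene was measured under a gene name here. In the lists fixed beforehand where no gene passed over all features or adjusted over the list alone, Keap1, stv, puc and kay were the 4 genes at an unadjusted limma p under 0.05. Over all 2377 named genes 91 had such a p, so these 4 do not by themselves set their lists apart.

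Lipid genes lay on both sides of 0. Lpin at 0.73 passed adjusted over the list alone and the lipase bmm stood at 0.40 ± 0.16, whereas apolpp lay at -0.54 ± 0.18. Of 9 genes in this list, 0 passed over all features and 1 adjusted over the list alone, 4 lay above 0 and 5 below (limma camera, adjusted p = 0.981). The median was -0.02 and the mean 0.01, and the median lay above 0 without the Cy3 array of replicate 3 (0.05) or the Cy5 array of replicate 1 (0.04). Turned, 4 of the 9 lay above 0. The gluconeogenic enzyme fbp, the 1 measured gene of the glycolysis list, stood at -0.25, and at -0.01 without the Cy5 array of replicate 1, with 0 past the test over all features or adjusted over the list alone. Of the 97 genes in the oxidative phosphorylation list 10 were measured. Of these 9 lay above 0, with ND-13A at 0.27, SdhBL at 0.22 and COX7AL at -0.23 (limma camera, adjusted p = 0.363). With the reverse-label arrays turned, 5 of the 10 lay above 0 and these 3 genes stood at -0.04, -0.09 and 0.02. The 10 need not stand for the list: signal over background was not used, so whether each is expressed in these females is not known. This holds for the ribosomal genes too. RpL32, RpS15Ab and RpS12 of 6 cytoplasmic ribosomal protein genes stood at 0.32, 0.28 and -0.22 (limma camera, adjusted p = 0.663), and mRpL16, mRpL13 and mRpL54 of the mitochondrial ribosome at -0.24, 0.17 and 0.13. Without 1 array each, RpL32 stood at 0.16, RpS12 at -0.01 and mRpL54 at -0.12. In these 3 lists 0 genes passed over all features and 0 adjusted over the list alone.

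Muscle was the 1 list of 11 past the test, shifted upward with a median of 0.27 and a mean of 0.38 (limma camera, adjusted p = 3.31e-05). With an estimated correlation the call was lost (limma camera, adjusted p = 0.883), and with fry the adjusted p was 0.141. The estimated correlation was -0.143 on 1 residual degree of freedom, so the lost call does not show correlation between the genes. Of its 8 measured genes 7 lay above 0. Act88F at 1.13 ± 0.15 and TpnC41C, a troponin C of muscle, at 0.74 ± 0.20 passed adjusted over the list alone, and 0 passed over all features. The Z-disc gene Zasp66 lay at 0.37 ± 0.15, paramyosin (Prm) at 0.35 ± 0.15, troponin T (up) at 0.18, TpnC73F at 0.17 and Tm2 at -0.01. Mlc-c, a cytoplasmic myosin light chain that is not particular to muscle, lay at 0.08. TpnC41C stood at 1.17 in replicate 1 and 0.31 in replicate 3, at 0.46 without the Cy5 array of replicate 1 and at -0.22 with the reverse-label arrays turned. With the reverse-label arrays turned, the list's median was -0.00351 and 4 of 8 lay above 0. None of 100 draws with no change gave a list at or under this adjusted p, although 15 had a list past the test. The draws randomise signs for each pair of adjacent spots, which removes correlation between genes. They therefore give no measure of chance for a list of correlated genes.

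**Figure D2:**
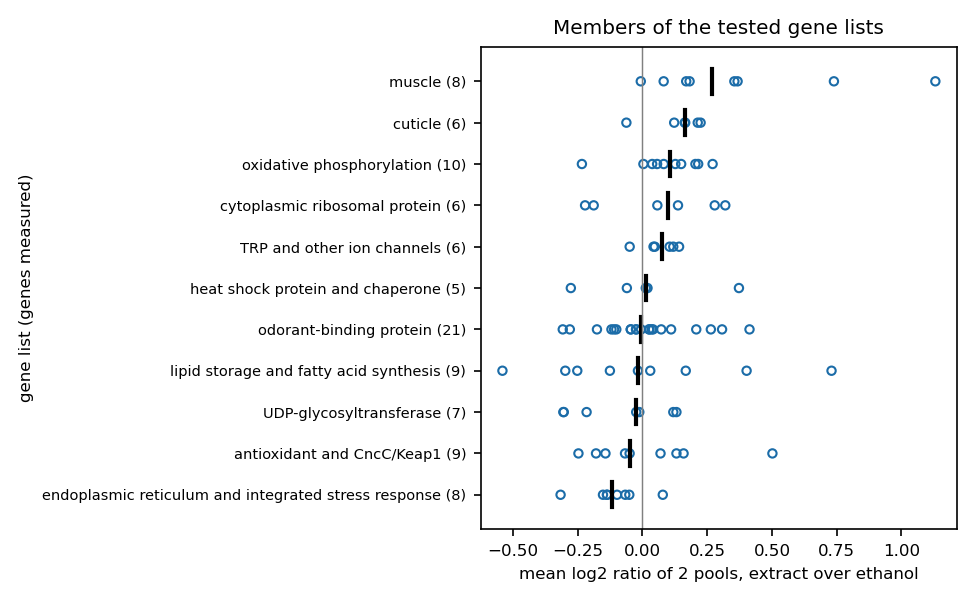
Mean log2 ratio of 2 pools, extract over ethanol (x axis), for each measured gene (open circles) of the 11 tested lists (y axis, with the number measured), and the list median as a black bar. The muscle median lies furthest right at 0.27, with Act88F at 1.13 as its highest member.

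Markers of other tissues gave no call. Male accessory gland and testis genes lay near 0, with Acp53C14a at 0.03, Acp36DE at -0.01 and dj at -0.02. All pools were of females, which lack these organs, so these genes are no test of the extract. The yolk receptor gene yl stood at -0.01, and the ovarian genes pum and exu at -0.28 and 0.22. Photoreceptor genes inaE, rdgB and rdgA lay at 0.20, 0.17 and 0.13, and the neuronal genes nSyb and cac at 0.25 and 0.05. The clock genes cwo, per and Pdp1 stood at 0.22, -0.16 and 0.10, with per at 0.05 without the Cy5 array of replicate 1. Of 6 ion channel genes, Sh, slo and eag lay at 0.14, 0.12 and 0.11 (limma camera, adjusted p = 0.644). Of 6 cuticle genes 5 lay above 0, and 3 with the reverse-label arrays turned, with TwdlT at 0.22, Lcp65Ag3 at 0.21 and TwdlW at 0.16 (limma camera, adjusted p = 0.185). Among 21 odorant-binding protein genes, Obp44a stood at 0.41 ± 0.18, Obp28a at 0.31 ± 0.15 and Obp19a at -0.31 ± 0.16 (limma camera, adjusted p = 0.981). In each of these 9 lists, 0 genes passed over all features and 0 adjusted over the list alone.

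The 2 pools agreed weakly across genes, which are not independent replicates. Over the 2377 named genes the Pearson correlation of the pool means was 0.175 and the Spearman correlation 0.151, and over all 13607 features they were 0.125 and 0.122. The 1 sign on all 4 arrays was held by 2144 features (15.8%), where chance alone gives 12.5%, and by 1638 (12%) with the reverse-label arrays turned. Of 83 genes named by the rules, 17 changed sign without 1 of the arrays, and so did the medians of 5 of the 11 tested lists. Adjacent spots, listed under the same gene for 2909 annotated pairs, correlated within an array at Spearman values of 0.221 to 0.367. The arrays of 1 dye swap correlated over all spots at a Pearson r of 0.0632 in replicate 3 and 0.0211 in replicate 1.

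**Figure D3:**
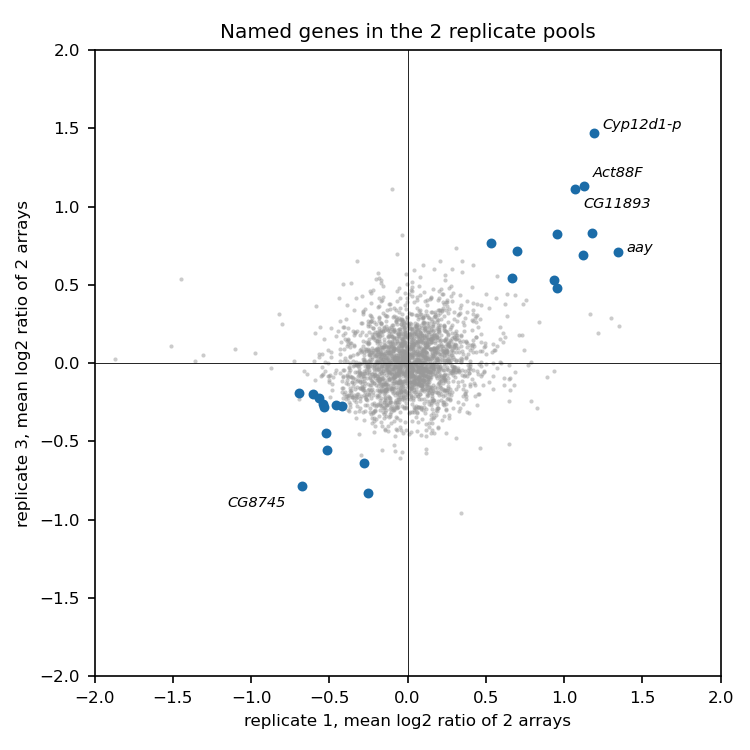
Mean log2 ratio of extract over ethanol in replicate 1 (x axis) and replicate 3 (y axis) for 2373 named genes in grey, with the 24 genes named by the size rule in blue; 4 genes lie outside the axes. Cyp12d1-p lies at 1.19 and 1.47, Act88F at 1.13 in both pools.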

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

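All tests in this part were chosen after the results were seen, with 2 exceptions. These are the comparison of single arrays by a fixed critical value and the reading with the reverse-label arrays turned. In 8 of 97 genes, lists and array measures, 1 array lay far from the other 3, where chance gives about 1 in 20, or 4.85. All 8 lay on the 2 arrays of replicate 1. On its Cy5 array Hsc70-2 stood at -1.8 (others 0.0949 to 0.403), fbp at -1.06 (-0.0723 to 0.068), pum at -0.524 (-0.218 to -0.186) and Obp44a at 1.23 (0.059 to 0.252). On its Cy3 array pch2 stood at -0.85 (-0.27 to -0.228), Dif at -0.426 (-0.156 to -0.105), rdgB at -0.274 (0.256 to 0.36) and the median of the UDP-glycosyltransferase list at 0.243 (-0.0697 to -0.0467).

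Cyp12d1-p, Act88F and CG11893 were among 9 features at 2-fold in both pools. Noise that is independent between arrays was argued against, since 0 of 100 draws with randomised signs reached 9 and the highest gave 5. Of 4 sign patterns that were run, the deposited one and those that turn 2 arrays, 1, the deposited one, gave as many as its 6 calls and the highest other gave 0, but 4 patterns are too few for a share under 0.05. A dye effect stays open: with the reverse-label arrays turned 0 features passed, which would also be seen if the ratios were deposited by dye and the extract had no effect of this size. The response to the extract and a dye effect cannot be told apart here, because the numerator of the ratios is unknown.

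Values beyond 3 log2 units in size numbered 74, of which 50 lay on the Cy5 array of replicate 1. For 20.3% of them the adjacent spot on the same array lay beyond 1 in the same direction. The share was also 20.3% for values between 1 and 1.5, 40.7% between 1.5 and 2 and 29.6% between 2 and 3. It does not set the 74 values apart as a group, and failed single spots stay open for the group. The share cannot speak for the most extreme single values. The lowest per array were -22.64 (replicate 3, extract in Cy5), -15.86 (replicate 1, extract in Cy3), -9.228 (replicate 1, extract in Cy5) and -3.186 (replicate 3, extract in Cy3). All values stayed in the main fit. No biological explanation was tested for these values.

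The higher muscle list was weighed against 3 explanations. For Act88F alone, the list without it gave a limma camera p of 0.000512 at the preset correlation and 0.173 with an estimated one of -0.143. The first p rests on an assumed correlation and the second on 1 residual degree of freedom, so this stays open. A like rise of all muscle RNA stays open too: the 8 ratios differed beyond their limma errors (chi-square heterogeneity p = 1.3e-06), but this rests on Act88F, and the other 7 gave 0.116. A larger share of flight muscle RNA stays open, since the comparison of Act88F with TpnC41C (chi-square heterogeneity p = 0.122) decides nothing: they are the 2 highest genes of the list, and TpnC41C is mainly of the jump muscle. These p-values treat 2 pools as enough to know each error, and a response of muscle to the extract was not separable from that share.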

How the results depend on the processing

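Settings named as added were chosen after seeing the data: adjacent spots averaged, named genes alone, duplicate spots within 1 log2 unit, the muscle list without Act88F or without TpnC41C as well, and the turned lists with an estimated correlation or fry. With the reverse-label arrays turned, 0 features passed, 0 were at 2-fold, the pools correlated at 0.0169, the muscle median was -0.00351 and Cyp12d1-p stood at 0.0606. In that reading 47 of the other 82 named genes changed sign. The limma calls, 6 as reported, numbered 42 with arrays scaled, 12 with the replicate block, 19 with each spot on its own and 15 at an adjusted p under 0.1. They numbered 181 with adjacent spots averaged, 10 with named genes alone and 170 with the duplicate filter. The first and last of these fits drew on 153 and 176 prior degrees of freedom, against 8.19 as reported. In 100 draws with no change they made calls in 37 and 67, at most 64 and 60, against 15 draws as reported, so part of these calls may be false. Features at 2-fold, 9 as reported, numbered 68 at 1.5-fold and 3 with named genes alone. The pools' correlation, 0.125 as reported, was 0.185 with adjacent spots averaged and 0.207 with the duplicate filter. The muscle median of 0.269 kept its value but not its call with an estimated correlation or fry, which left 0 lists past the test with either, also with the reverse-label arrays turned. Without Act88F the muscle median was 0.182, past the test at the preset correlation and not at an estimated one, and without TpnC41C as well it was 0.176 and not past it (limma camera, adjusted p = 0.0827). Leaving out single arrays or a pool gave 0 to 11 calls, 8 to 94 features at 2-fold, a pools' correlation of 0.055 to 0.131, a muscle median of 0.245 to 0.315 and Cyp12d1-p at 1.19 to 1.47. The 0 calls came without the Cy3 array of replicate 3, where Cyp12d1-p lost its call, the 11 without the Cy5 array of replicate 1, the correlation of 0.055 without the Cy3 array of replicate 1, and 52 and 94 features at 2-fold from replicates 3 and 1 alone, which have no test. The causes were not tested. No centring, the median of a gene's spots, and robust eBayes kept the side of the threshold for all 82 other named genes, the lists and the counts within 1.5 times. With the replicate block Act88F, CG11893 and CG31904 also passed and no other named gene changed its call; with a dye term added, or each spot on its own, Act88F and CG11893 passed. Scaling added 6 named genes, and Act88F also passed without the Cy5 array of replicate 1. The arrays of a pool share their RNA by the labels, yet their consensus correlation was -0.244, and the dye-term fit used the same estimate. Neither block fit therefore held the arrays of a pool as 1 replicate. They had 3 and, with the dye term, 2 residual degrees of freedom, against 1 as reported. Their median standard errors were 0.127 and 0.131, against 0.153. Their added calls are no evidence beyond 2 pools. Missing values were 0, so the alternative for them gave no value, and single spots gave none for lists. Signal over background was not used here, so what it limits is not known.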

Other observations

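The test in this part was written down before the values of its 8 genes were seen, but the list was added after the gene table had been seen, and the turned values were computed after the result. Genes of fasting and autophagy lay mostly above 0, with 7 of 8 measured members above it and a median of 0.10; with the reverse-label arrays turned, 4 of 8 lay above 0. Sesn, the sestrin that restrains TOR signalling, stood at 0.42 ± 0.15 (limma, adjusted p = 0.578) and Atg18a, an autophagy gene, at 0.39 ± 0.15 (limma, adjusted p = 0.617). The transcription factor gene foxo lay at 0.17, Atg101 at 0.12, Atg4b at 0.09, REPTOR at 0.08, Atg9 at 0.02 and Atg13 at -0.04.

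A hypothesis is that the flies sprayed with extract may have fed less, which would also raise the lipase genes bmm and CG5966 and Lpin. These genes, all above 0 on 4 of 4 arrays, prompted the hypothesis and are no support for it. With the reverse-label arrays turned, bmm stood at -0.006, CG5966 at 0.16 and Lpin at 0.08. The 8 fasting and autophagy genes gave an unadjusted limma camera p of 0.0149, upward, as the hypothesis predicts. The fixed lists were judged by a camera p adjusted over all tested lists, and this added list was not part of that adjustment. Its p is therefore not comparable with theirs, and the list is not counted as past the test. The camera p was 0.241 with an estimated correlation, which rests on 1 residual degree of freedom. It was 0.256 with the reverse-label arrays turned. No gene of the list passed the test over all features, with Sesn and Atg18a at an unadjusted limma p of 0.0202 and 0.029. Feeding was not measured, and the direction rests on the unsettled numerator of the ratios.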
